A study of Mus musculus with 2 samples.

How the data were processed

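RNA was measured in hepatocytes of male FVB mice on Affymetrix Mouse Genome 430 2.0 arrays, which report each transcript through probe sets near its 3′ end. Per the labels' protocols, mice of 6 to 8 weeks received a hydrodynamic tail vein injection, a rapid infusion of a large volume that drives plasmid DNA into hepatocytes. It held 10 µg of a plasmid encoding Ezrin T567D and 0.8 µg of a plasmid encoding the Sleeping Beauty transposase in 2 ml of saline. Ezrin links the plasma membrane to the actin cortex, and T567D replaces the threonine that is phosphorylated in the active protein with an acidic residue. Hepatocytes were released with collagenase 1 week later and sorted by GFP fluorescence, which the labels equate with Ezrin T567D. Biotin-labelled cRNA was made from 6 µg of Trizol-extracted total RNA.

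The deposited values are probe set intensities on a linear scale, and MAS5 made them, per the submitters' processing notes. The 2% trimmed mean was 500.0 in both arrays, so each array had been scaled to one overall level. Software version, detection calls and other settings are not given in the sources used here. Such scaling sets the average signal equal and cannot show a shift of the whole transcriptome. It also leaves differences that depend on signal in place, and the median log2 ratio was -0.12 over 346 genes with a mean signal above 10000 and 0.09 over 4454 genes with a mean signal up to 1000. Random gene lists were matched on signal for that reason.

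Groups came from the group label, EzrinT567D negative or EzrinT567D positive, with 1 array in each. The labels conflict on a point that bears on the comparison. The growth protocol gives a chow diet for both samples and the source names give 1 week after injection, but the description fields give 2 months for both, with chow for the negative and a fast food diet for the positive sample. A difference in diet is therefore not excluded. How many mice were used, whether RNA was pooled and whether both sorted fractions came from the same livers are not given in the sources used here.

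Of 45101 probe sets on each array, 34945 carried 1 gene symbol, 932 several and 9160 none, and 64 were controls. Symbols of 34754 probe sets were matched by Entrez ID to a RefSeq gene table and 0 changed. Probe sets with several or no symbols were left out of gene values. No genome build is named for the arrays in the sources used here, so no coordinates are given. A background floor was set in each array at the 95th percentile of 84 probe sets for olfactory, vomeronasal, taste and trace amine receptors, at 252.66 in the negative and 334.04 in the positive array. The brightest probe set stood for its gene, also in deciding whether the gene exceeded the floor. Of 18193 genes, 10204 exceeded the floor in at least 1 array and 8353 in both. The other 1851 have only a bound, computed by raising the dim signal to its floor. Because the floors differ, that bound pointed away from the measured side for 899 genes, whose log2 ratio was set to 0. Setting them to 0 was chosen after the data were examined. The rule fixed beforehand kept the bounds as computed, and it was run as an alternative. The settings with these ratios at 0 are called the main settings below.

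The comparison is the log2 ratio of the positive over the negative array, with genes counted at 2-fold (a log2 ratio of 1). With 1 array per group no test between the groups exists, and no p-value or replicate error is given. The available error is technical: over 3182 genes with at least 2 probe sets above the floor in both arrays, the log2 ratios of the 2 brightest probe sets differed with an SD of 0.42 and a median absolute difference of 0.26, and 2.77% differed by at least 2-fold. The SD was 0.46 where the dimmer probe set was under 1000 and 0.33 where it was 1000 or more. It includes differences between transcripts and leaves out the spread between animals.

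Gene lists, 40 in all, were fixed before the data were examined. They cover the pathway in the series title, hepatocyte functions and zones, stress responses and other liver cell types. For each list with at least 3 members above the floor, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. A list is said to stand apart below the 2.5th or above the 97.5th percentile, as a description of these 2 arrays. Of the lists, 39 could be placed, and chance would give 1.95 if genes were exchangeable. Genes of a list are correlated and lists share members, so 1.95 is not a firm chance level. The genes named were also fixed by rule: the 12 highest and 12 lowest ratios among genes above the floor in both arrays, without predicted genes or genes whose probe sets differ in sign, the 4 highest bounds in each direction, up to 4 members with the largest ratios per list, and a set of ezrin, Hippo and liver genes. Further genes named from a list serve as examples and were picked after their values were seen.

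The alternatives were quantile normalization, a loess correction of the ratio on signal (fraction 0.3) and equal medians above the floor. Others were a floor at the 99th percentile of the receptor probe sets or at the median of all probe sets, and no floor with a pseudocount of 16. The rest were only genes measured in both arrays, the mean over a gene's probe sets, and random lists not matched on signal. A further one kept only probe sets with names not ending in _s_at, _x_at or _a_at. Sets with these endings are called probe sets of shared or mixed probes below, whether or not they bind other genes. In addition, 3 alternatives were added after seeing the data: 1 floor for both arrays, the bounds as computed (the rule first fixed), and lists without members of the zonation lists. The procedure was tested on a simulated positive array, made from the negative one with noise on the log2 ratio of SD 0.327 for signals under 1000 and 0.232 for others. These are the SDs between probe sets of a gene divided by the square root of 2. The test therefore leaves out the spread between animals and errors shared by all probe sets of a gene. Since the simulated array came from the negative one, the gap between the real floors is absent too. The shares that follow are thus not error rates for the real counts. Of 10013 genes above the floor in the simulation, 200 were changed, 100 by each fold. These were drawn only from genes above the floor in the real negative array. At 2-fold, 72.0% of the 3-fold and 5.0% of the 1.5-fold differences were counted in the right direction, against 0.102% of unchanged genes in either direction. Of 200 unchanged lists 6.0% stood apart. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 were used.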

Results

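Transcript levels were compared between hepatocytes that carried a phosphomimetic ezrin, Ezrin T567D, and hepatocytes sorted as negative for it 1 week after plasmid injection. The series title places the comparison in the context of ezrin phosphorylation, the Hippo pathway and its effector Yap. Each group held 1 array, so every difference below compares 2 arrays without replicate error, and the diet label of the positive sample conflicts between fields. Signals ran from 0.2 to 71329.8 in the negative and from 0.1 to 68451.9 in the positive array, with medians of 174.2 and 187.6. The floor was exceeded by 18052 probe sets (40.1%) in the negative and 15764 (35.0%) in the positive array. The ratio of 3′ to 5′ signal, a sign of RNA integrity, was 0.970 and 0.864 for Actb and 3.46 and 3.13 for Gapdh in the negative and positive arrays. The 9 probe sets for hybridisation spikes had log2 ratios from -0.10 to 0.12.

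The transgene itself could not be followed. Both Ezr probe sets lay below the floor in both arrays, with signals of 135.3 and 15.7 for 1450850_at and of 7.6 and 13.6 for 1456725_x_at (negative, then positive). Neither the species of the ezrin sequence nor its 3′ end is given in the sources used here, so probes for the 3′ end of the mouse transcript need not bind it. The arrays therefore provide no check of the sort labels through Ezr. Among the relatives of ezrin, radixin (Rdx) was bright, at 7171.3 and 8001.6, but its 3 probe sets had log2 ratios of 0.16, -0.05 and -0.31. Moesin (Msn) read 293.2 and 269.1, above the floor only in the negative array.

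Most genes had similar signals in the 2 arrays. Across the 8353 genes above the floor in both arrays, log2 signals correlated with Pearson's r = 0.969 (across genes, which are not independent replicates), and the 10th and 90th percentiles of the log2 ratios were -0.40 and 0.46. At least 2-fold higher signals in Ezrin T567D-positive hepatocytes were counted for 133 genes (1.30% of those above the floor), 91 of them measured in both arrays and 42 as bounds. At least 2-fold lower signals were counted for 60 genes (0.588%), 51 measured and 9 as bounds. Because the floor was lower in the negative array, bounds are larger on the higher side by construction. The gap also favours higher ratios among measured genes. A gene between 252.66 and 334.04 in the negative array counts as measured only if above 334.04 in the positive array. With 1 floor for both arrays, chosen after seeing the data, the counts were 82 and 60. After the loess correction the counts were 90 and 68, which put 57.0% of them on the higher side, against 68.9% as deposited. The 99th percentile floor left 79 higher genes, and without a floor the counts were 1131 and 1226.

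Among the genes measured in both arrays, the cytochrome P450 genes Cyp2c38 (271.0 in the negative to 1207.1 in the positive array, 4.45-fold) and Cyp2c39 (498.3 to 2151.1, 4.32-fold) had the highest ratios, followed by the dicarboxylate transporter Slc13a3 (3.52-fold) and Gulo, the last enzyme of vitamin C synthesis (1549.4 to 5401.6, 3.49-fold). The fatty aldehyde dehydrogenase Aldh3a2 was 3.39-fold higher, the glutathione transferases Gstm3 and Gstm2 3.34-fold and 3.21-fold, the retinol dehydrogenase family member Rdh9 3.17-fold and the vasopressin receptor Avpr1a 3.13-fold, the last in 2 probe sets. Tcp11 (3.07-fold), the monocarboxylate transporter Slc16a8 (280.2 to 840.1) and the lipoprotein receptor Vldlr (2.87-fold) completed the 12 highest. Negative signals of Cyp2c38, Slc13a3, Tcp11, Slc16a8 and Vldlr, from 268.8 to 321.3, were near the floor, and with the 99th percentile floor the log2 ratio of Cyp2c38 was 1.82, below the 2.11 of Cyp2c39. Genes whose brightest probe set was below the floor in the negative array were led by Serpina7, the thyroxine-binding globulin, at least 5.35-fold higher, and by the kinase Ptk2b (at least 3.99-fold), Pdk4 (at least 3.52-fold) and Btbd19 (at least 3.10-fold).

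Among the lowest ratios, the mitochondrial aldehyde dehydrogenase Aldh1b1 read 2408.2 in negative and 540.8 in positive hepatocytes (4.45-fold lower), and the histidine-degrading enzyme Hal read 4455.1 and 1248.3 (3.57-fold lower). Etnppl, which degrades phosphoethanolamine, was 3.34-fold lower, the glucuronosyltransferase Ugt2b38 3.30-fold and the glycine decarboxylase Gldc 3.07-fold. The protease Ctsc was 3.05-fold lower, the nicotinamide methyltransferase Nnmt 2.96-fold, Sh3bp5 2.91-fold, Gas2 2.77-fold, the ubiquitin ligase Mib2 2.70-fold, the E-cadherin gene Cdh1 2.63-fold and the steroid dehydrogenase Hsd17b6 2.60-fold. Genes whose brightest probe set was below the floor in the positive array included Cryl1 (at least 3.60-fold lower), Smtnl2 (at least 2.57-fold), Man2b2 (at least 2.54-fold) and Mvk (at least 2.34-fold). Averaged over all probe sets of a gene above the floor, the log2 ratios were -0.68 for Ctsc, -0.99 for Sh3bp5 and 0.98 for Ptk2b, and without probe sets of shared or mixed probes that of Cryl1 was -0.996. With the 99th percentile floor, Man2b2 (-0.99) and Mvk (-0.87) were also under 2-fold. The Cyp2c, Gstm, Ugt2b, Rdh and Saa families have close paralogs whose transcripts one probe set may not separate.

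**Figure D1:**
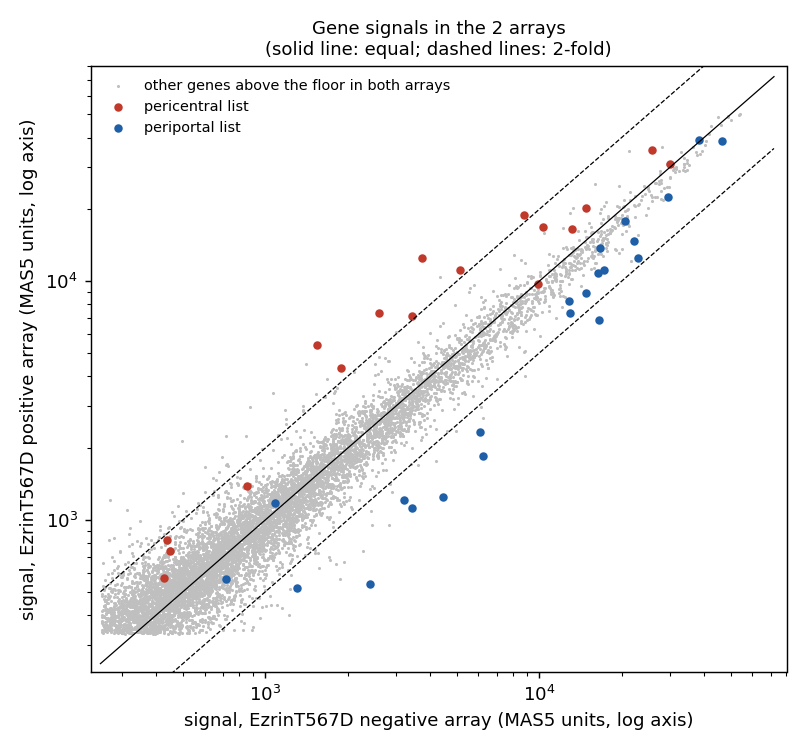
Signal of each gene in Ezrin T567D-negative (x axis) and Ezrin T567D-positive (y axis) hepatocytes, both on log scales in MAS5 intensity units, 1 array per group, for the 8353 genes above the floor in both arrays, with pericentral list members in red and periportal ones in blue. The solid line marks equal signals and the dashed lines 2-fold, and most genes lie between the dashed lines, with 91 genes on or above the upper and 51 on or below the lower one.

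Genes of the zones of the liver lobule separated the 2 arrays in opposite directions. Pericentral genes, which hepatocytes around the central vein express most, were higher in the positive array: 16 of 17 members were higher and 1 lower, 7 of them by at least 2-fold, with a median log2 ratio of 0.73 (1.66-fold) at percentile 100 of matched random lists. Gulo and Gstm3 led, followed by the hepatokine Lect2 (2590.8 to 7389.3, 2.85-fold), Cyp7a1, the rate-limiting enzyme of bile acid synthesis (2.31-fold), the glutamine synthetase gene Glul (8783.1 to 19020.7, 2.17-fold), Cyp1a2 (2.16-fold) and Oat (2.07-fold). Cyp2e1 was 1.38-fold higher, and Cyp27a1 had a log2 ratio of -0.03. Periportal genes, expressed most near the portal vein, were lower: 20 of 22 members were lower and 2 higher, 8 of them by at least 2-fold, with a median of -0.68 (1.60-fold lower) at percentile 0.0. Aldh1b1, Hal, Etnppl and Ctsc led, and Hsd17b13 (2.52-fold), the immunoglobulin receptor Pigr (16534.4 to 6870.6, 2.41-fold), Cyp2f2 (1.82-fold) and the urea cycle enzymes Asl (1.77-fold) and Arg1 (1.66-fold) were also lower. Of the 12 highest genes 2 are in the pericentral list and 0 in the periportal list, and of the 12 lowest 6 are in the periportal list and 0 in the pericentral list.

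Targets of WNT and beta-catenin signalling, a pathway active around the central vein, were higher as well. Of 13 members above the floor, 12 were higher and 0 lower, with 4 at 2-fold or more and a median of 0.49 at percentile 100. The transcription factor Tbx3 was 2.75-fold higher (604.3 to 1659.0), and the feedback regulator Rnf43 at least 2.73-fold. The list shares 4 members with the pericentral list, among them Lect2, Glul and Axin2. Without them 8 of the remaining 9 were higher, and the median was 0.46 at percentile 99.8. Only members named in the zonation lists were removed, so this does not separate the list from the zonal shift. With the 99th percentile floor the median of the full list was 0.84.

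**Figure D2:**
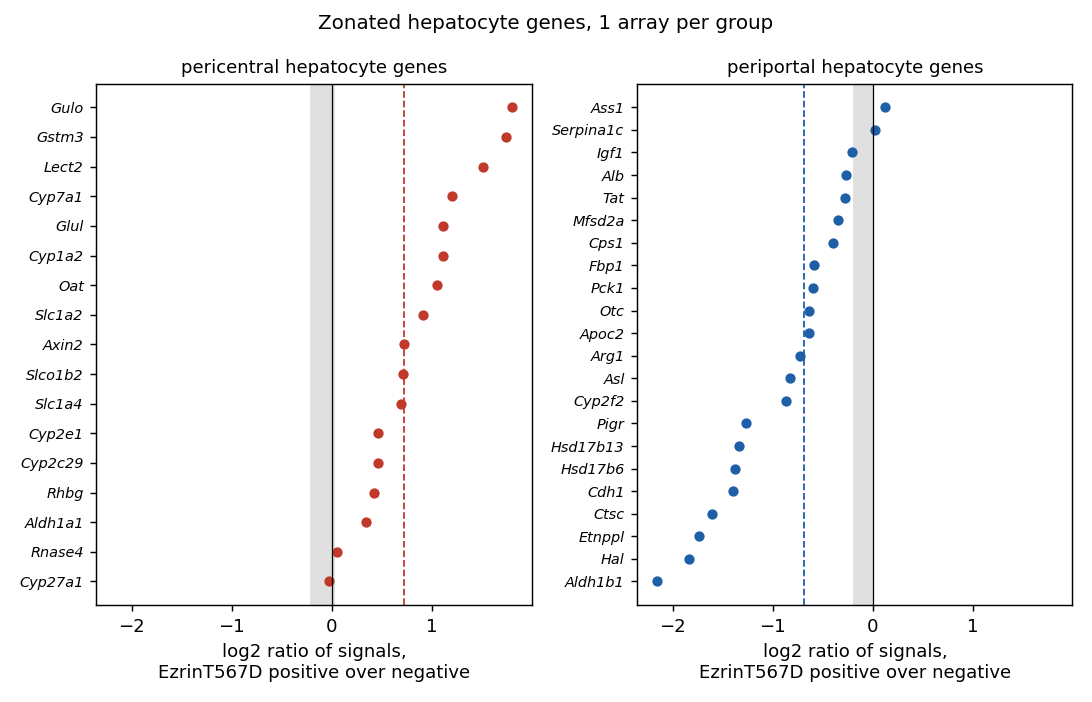
Log2 ratio of the positive over the negative array (x axis) for each pericentral gene and each periportal gene above the floor, 1 point per gene from 1 array per group. Of the pericentral genes 16 of 17 lie to the right of 0, and of the periportal genes 20 of 22 lie to the left.

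For the Hippo pathway, the kinase cascade that restrains Yap, the arrays showed no common direction. The list had a median of 0.00 over 22 members at percentile 45.7, with 9 higher and 10 lower. Yap1 itself read 2512.9 and 2363.3 (log2 ratio -0.09, probe set 1448363_at), while its other probe set lay below the floor. The upstream kinase Stk4 was lower in both probe sets above the floor (-0.78 and -0.45), and the transcription factor Tead1 read 591.9 and 359.4 (-0.72). Probe sets differed in sign for Lats2 (-0.27, 0.23 and 0.34), Sav1 (-0.47 and a bound of 0.45), Mob1a (-0.28, -0.33 and 0.09) and the merlin gene Nf2 (0.86, 0.01 and a bound of -0.23), whereas both for Lats1 were higher (0.16 and 0.40). Vgll4, a TEAD cofactor, had a ratio of 0.43. Wwtr1, Tead3 and Tead4 lay below the floor in both arrays, Tead2 exceeded it only in the negative array (257.7 and 268.3), and Stk3 has no probe set of its own.

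Of the 14 Yap and TEAD target genes above the floor, 6 were higher, 4 lower and 4 without a direction, and the median of 0.00 lay at percentile 44.2. Ccn1 (Cyr61), a matricellular protein, was higher in all 4 of its probe sets, with log2 ratios of 1.08, 1.20, 1.11 and 1.56 (1366.8 to 2881.2 in the brightest). Amotl2 was higher by 0.34 and Gadd45b by at least 0.90, whereas Arhgef17 was lower (a bound of -0.72) and so was Notch2 (-0.28). Ccn2 (Ctgf), Ankrd1, Birc5 and Sox9 were below the floor in both arrays, and Areg has no probe set of its own. The 4 without a direction (Ajuba, Ptpn14, Fjx1 and Dock5) read lower in the positive array, below its floor. They were set to 0 by the rule chosen after the data were examined. With the bounds as computed, as first fixed, the list stood apart higher. That rule gives these 4 positive ratios through the gap between the floors. Over the 7 targets measured in both arrays the median was 0.34 at percentile 98.7. This filter leaves out Arhgef17 and Nt5e, which were lower, and Gadd45b, which was higher. The position of this list therefore depends on how genes near the floor are treated.

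Ezrin, radixin and moesin with their binding partners had a median of 0.14 over 12 members, 8 of them higher and 3 lower, at percentile 97.51, just past the limit. Nf2 (0.86, with other probe sets at 0.01 and a bound of -0.23), Icam2 (a bound of 0.53), Icam1 (0.46) and the scaffold Pdzk1 (0.37) had the largest ratios. The list stood apart under 5 of 13 alternatives, and its median was 0.08 without a floor. It did not stand apart with the bounds as computed, the rule first fixed, or over genes measured in both arrays (percentile 96.0). Notch pathway genes had a median of 0.14 over 10 members at percentile 84.7, with 6 higher and 3 lower. Notch1 (0.65) and Hes1 (0.51) were higher, Hes5 had a bound of 0.44, and Rfng was lower (-0.38).

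Amino acid breakdown and the urea cycle were lower in the positive array. Of 28 members 23 were lower and 5 higher, with a median of -0.33 (1.26-fold lower) at percentile 0.0. Next to Hal, the aspartate aminotransferase Got1 (2847.5 to 1417.7, 2.01-fold), the urocanase Uroc1 (1.79-fold) and Asl were lowest. Without the 7 members shared with the zonation lists, 17 of 21 were lower and the median was -0.29. Whether the remaining members are zonated was not tested, so this does not separate the list from the zonal shift. Oxidative phosphorylation genes were lower by small amounts: 27 of 30 were lower and 3 higher, none by 2-fold, with a median of -0.27 (1.21-fold lower) at percentile 0.01. Uqcrfs1 (1.65-fold), Sdhb (1.36-fold), Ndufb9 (1.35-fold) and Ndufb8 (1.33-fold) were lowest. The median was -0.18 after quantile normalization and -0.17 after loess, and the list still stood apart.

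Acute phase genes and complement and coagulation genes were lower as lists. Acute phase genes had a median of -0.23 over 26 members at percentile 0.28, with 21 lower and 5 higher. Saa2 (-0.83), Saa1 (-0.81) and the metallothionein Mt1 (-0.72) were lower, while Saa3 was 2.45-fold higher (317.4 to 778.8). Complement and coagulation genes had a median of -0.19 over 33 members at percentile 1.92, with 25 lower and 8 higher, led by C2 (-0.81), F7 (-0.60), Cfi (-0.53) and Hc (-0.50). The acute phase median was -0.15 after quantile normalization and -0.12 after loess, where the list still stood apart. Its call ended with the mean over probe sets (-0.15) and without probe sets of shared or mixed probes (-0.18), and that for complement and coagulation after quantile normalization (-0.080) and loess (-0.074).

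Lipid and glucose metabolism showed single genes at 2-fold, and none of the lists stood apart with the main settings. Fatty acid and triglyceride synthesis had a median of -0.05 over 21 members (percentile 63.3), with the citrate lyase Acly (2.21-fold lower) and the desaturase Fads2 (2.06-fold lower) against Pnpla3 (2.08-fold higher) and the carbohydrate-responsive factor Mlxipl (1.99-fold higher). Fatty acid oxidation and PPARA targets had a median of -0.08 over 23 members (percentile 34.3), with Pdk4 and the thioesterase Acot2 (2.23-fold) higher and Cpt2 (-0.45) and Ehhadh (-0.31) lower. Gluconeogenesis and glycolysis had a median of -0.15 over 20 members (percentile 12.3), with Igfbp1 (4343.9 to 10461.9, 2.41-fold), Pfkfb3 (2.23-fold) and Pkm (2.21-fold) higher and the gluconeogenic enzyme Pck1 (1.51-fold) lower. Negative signals of Pnpla3 (254.7), Pfkfb3 (265.5) and Pkm (289.9) were near the floor of 252.66. Cholesterol synthesis and uptake had a median of -0.18 over 19 members (percentile 4.37), 14 of them lower, among them Mvk, Mvd (-0.70) and Stard4 (-0.59), while Fdps was higher (0.44). Bile acid genes had a median of -0.03 over 23 members (percentile 83.7), with Cyp7a1, Slco1b2 (0.71), Hsd3b7 (0.48) and Abcb11 (-0.42) the farthest from 0. Cytochrome P450 and drug metabolism genes had a median of -0.05 over 25 members (percentile 93.0), with Cyp1a2, Cyp2c50 (0.98), Cyp2f2 and Sult1a1 (-0.65) the farthest. In these lists, except cholesterol, the mean log2 ratio was above 0 while the median was below it. With the mean over probe sets, cholesterol genes stood apart lower (-0.18, percentile 0.9) and bile acid genes higher (0.12, percentile 99.6), and without probe sets of shared or mixed probes gluconeogenesis and glycolysis stood apart lower (-0.20, percentile 1.23).

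Immediate early genes, which are induced within minutes to hours of a stimulus and also by tissue dissociation, were higher in the positive array. Of 27 members 22 were higher and 5 lower, 5 by at least 2-fold, with a median of 0.42 (1.34-fold) at percentile 100. Maff (851.8 to 2252.6, 2.64-fold), Klf6 (2.36-fold), Ier2 (2.35-fold) and Atf3 (1674.5 to 3912.9, 2.34-fold) led. Targets of NF-kB and chemokines had a median of 0.22 over 11 members at percentile 97.9, with 6 higher and 4 lower, but stood apart under 4 of 13 alternatives. This list did not stand apart with the bounds as computed, the rule first fixed. Its median was 0.13 after quantile normalization, 0.10 after loess, 0.08 with the floor at the median of all probe sets and -0.017 without a floor. Ccl9 was 2.33-fold lower (6230.2 to 2678.3), whereas Nfkb2 (0.69), Ccl2 (0.63, from 279.8 near the floor) and Ccl5 (a bound of 0.49) were higher. Interferon response genes had a median of -0.06 over 16 members at percentile 23.2, with Ddx58 (-0.69), Tap1 (-0.54) and Bst2 (-0.46) lower and Cxcl10 at a bound of 0.42.

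Genes of the fetal and progenitor liver were higher, from low signals. Of 8 members above the floor 7 were higher and 1 lower, with a median of 0.70 at percentile 99.99. The noncoding RNA Meg3 read 279.0 and 670.5 (2.40-fold higher), Igf2bp3 309.8 and 526.0 (1.70-fold) and Gpc1 368.9 and 614.3 (1.67-fold), and Igf2bp1 was at least 1.65-fold higher. Afp and Gpc3, both classical fetal markers, lay below the floor in both arrays. Without probe sets of shared or mixed probes the median was 0.39 and the list no longer stood apart.

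Cell cycle genes had a median of 0.23 over 16 members at percentile 96.6, within the range of random lists, although 14 were higher and 2 lower. The replication licensing genes Mcm4 (255.7 to 658.0, 2.57-fold) and Mcm7 (413.5 to 938.9, 2.27-fold) were higher, as were Mki67 (at least 2.14-fold) and Rrm2 (at least 2.00-fold). The negative signal of Mcm4 was near the floor. Targets of p53 had a median of 0.12 over 12 members at percentile 91.4, with the antiproliferative gene Btg2 (2.09-fold), Trp53inp1 (2.05-fold) and Cdkn1a (at least 1.55-fold) higher and Sesn2 (1.61-fold) lower. The unfolded protein and integrated stress responses had a median of -0.03 over 21 members at percentile 76.7. Of these 7 were higher and 13 lower, with Ppp1r15a (0.72), Ddit3 (0.69), Sesn2 and Trib3 (0.56) the farthest from 0, and the mean of 0.02 was on the other side of 0 from the median. Under other settings the cell cycle list stood apart higher in 2 of 13 cases and the p53 list in 3.

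Hepatocyte identity genes had a median of -0.05 over 26 members at percentile 91.2, with 9 higher and 17 lower. Foxa2 (-0.69), Nr1i3 (0.61), Nr1i2 (0.49) and the urea cycle enzyme Cps1 (-0.39) were the farthest from 0. Albumin (Alb) read 46434.5 and 38679.3, a log2 ratio of -0.26.

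No list of markers of other liver cells stood apart with the main settings. Kupffer cell and macrophage markers had a median of -0.10 over 13 members at percentile 8.24, with Ctss (768.9 to 345.3, 2.23-fold) and C1qb (-0.67) lower, Fcer1g (0.71) higher, and 8 lower against 4 higher in all. This list stood apart lower under 3 of 13 alternatives, with a median of -0.24 at percentile 0.4 with the floor at the median of all probe sets, -0.30 without a floor and -0.18 with 1 floor for both arrays. Markers of sinusoidal endothelium had a median of 0.12 over 20 members at percentile 89.3, with Bmp2 (0.89), Cdh5 (0.84), Aqp1 (0.60) and a bound for Cyyr1 of 0.52. Negative signals of Bmp2 (274.7), Cdh5 (283.0) and Aqp1 (257.6) were near the floor. Stellate cell and fibroblast markers had a median of 0.11 over 12 members at percentile 78.7, with Rgs5 (-0.79) and Col1a1 (0.41) the farthest from 0. Cholangiocyte markers had a median of -0.02 over 6 members at percentile 63.0, from -0.19 for the bound of Cldn7 to 0.18 for Krt8. Krt7, Krt19, Sox9, Epcam and Spp1 were not among these 6. Krt8 and Krt18 were bright (5659.0 and 11517.8 in the negative array), so the median says little about cholangiocytes. Lymphocyte markers had 4 members above the floor, with a median of 0.27 at percentile 86.8 and Cd2 at 0.66. Of the neutrophil markers 2 exceeded the floor in 1 array each, which is too few for a median.

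**Figure D3:**
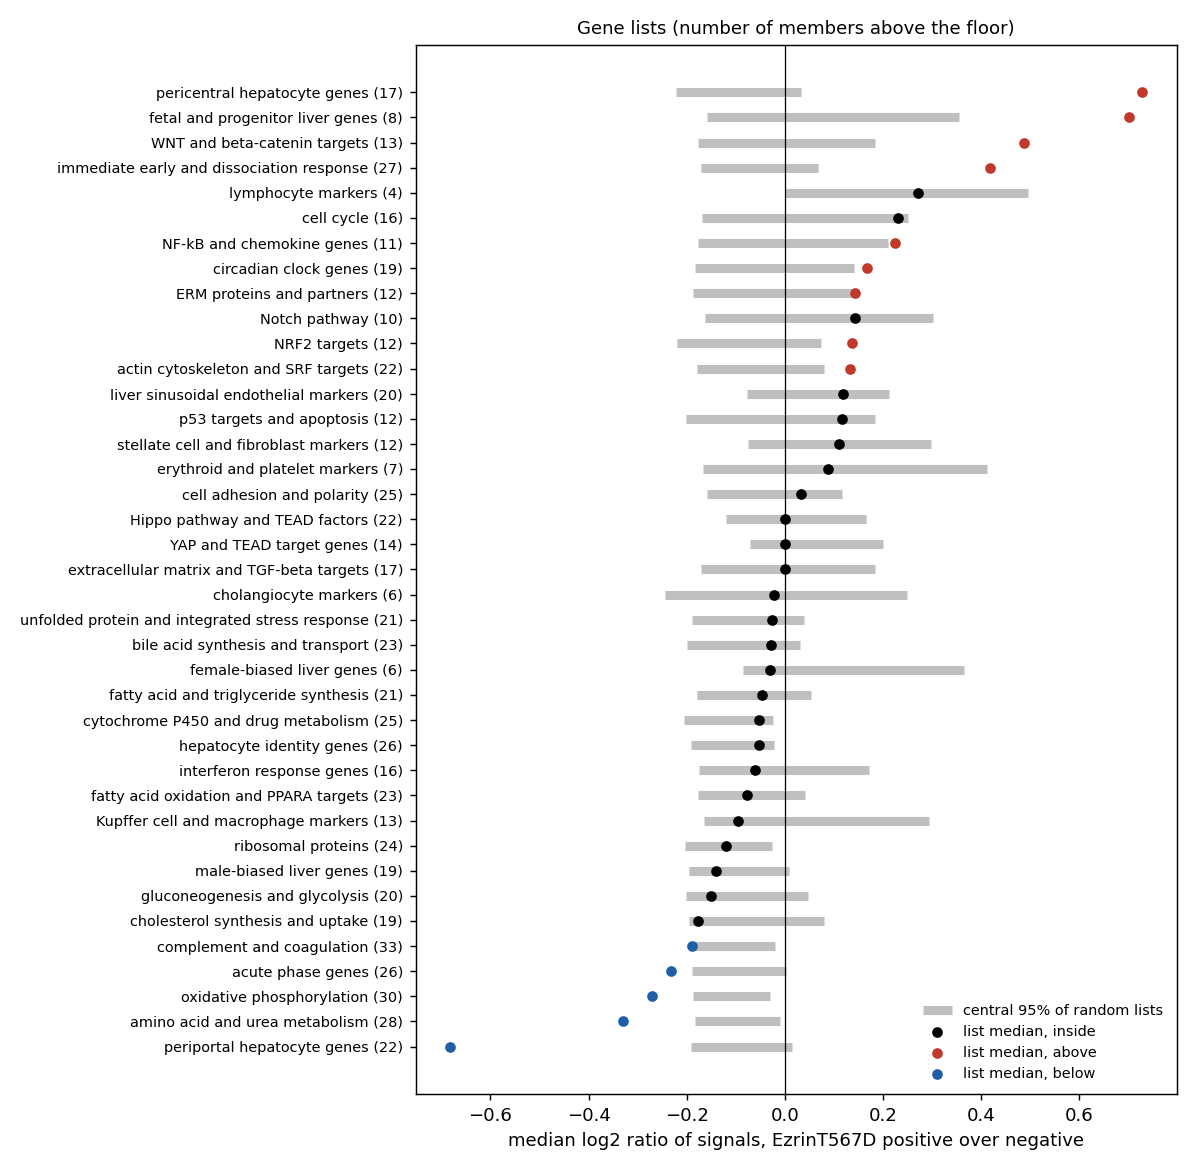
Median log2 ratio of the positive over the negative array (x axis) for the 39 gene lists with at least 3 members above the floor, 1 array per group, with the number of such members in parentheses and grey bars for the central 95% of medians from 10000 signal-matched random lists. Of the lists 14 lie outside the bars, 9 above (red) and 5 below (blue). Those of ERM proteins and of NF-kB did not stand apart with the bounds as computed, the rule first fixed. Exchangeable genes would give 1.95 by chance, but genes of a list are correlated and lists share members.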

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

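Both results here come from probe sets with no gene name in the annotation used, which the comparisons of named genes leave out. The probe set 1441366_at read 435.3 in negative and 8658.4 in positive hepatocytes, a log2 ratio of 4.31 or 19.9-fold. That was the highest ratio among all 14931 probe sets above the floor in both arrays, where the next was 2.21. Which transcript this probe set measures is not known here, nor whether it is a mouse transcript or part of the injected plasmids, so the ratio cannot be read as the change of a mouse gene. Of 1707 unnamed probe sets above the floor, 55 were at least 2-fold higher in the positive array and 9 at least 2-fold lower. These counts include bounds, which the unequal floors make larger on the higher side by construction. No explanation was tested for either result.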

How the results depend on the processing

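No paired analysis was possible because each group holds 1 array, and for the same reason no array could be left out. The pericentral, periportal, WNT, immediate early, amino acid and oxidative phosphorylation lists kept their direction and stood apart under each alternative run, with pericentral medians from 0.69 to 0.82 and periportal medians from -0.72 to -0.57. None of the 32 named genes reversed over 335 alternative values, which says little because they were chosen for extreme ratios in these arrays. Of the values, 12 moved by more than 1 SD of the probe set spread, and 6 genes came under 2-fold in some alternative. The number of lists standing apart ranged from 10 to 16. Other scaling moved the median of all genes to -0.03 at most. Signal over background limited the counts. Higher genes numbered 79 with the 99th percentile floor, 232 with the floor at the median of all probe sets and 1131 without a floor, and 82 with 1 floor for both arrays, an alternative chosen after seeing the data. Lower genes numbered 154 with the median floor, 1226 without a floor and 38 with the mean over probe sets. A lower floor adds dim genes and a higher one removes them by construction, while the cause of the count of 38 was not tested. The Yap and TEAD target list newly stood apart in 6 of 13 alternatives, with medians of 0.32 (99th percentile floor), 0.25 (median floor) and 0.34 (genes measured in both arrays). The others were 0.21 (mean over probe sets), 0.28 (1 floor) and 0.27 (bounds as computed, the rule fixed before the data were examined). With the bounds as computed, Ajuba, Ptpn14, Fjx1 and Dock5 were positive only through the gap between the floors. The list did not stand apart after quantile normalization (0.00, percentile 57.9) or loess. The NF-kB median reversed to -0.017 without a floor; the cause was not tested. Ezr stayed below the floor in both arrays under all 4 alternatives run for it.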

Other observations

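Clock, redox and cytoskeletal genes had medians slightly above 0, with calls that depended on the processing. Circadian clock genes had a median of 0.17 over 19 members at percentile 98.9, with 15 higher and 4 lower. The repressor Nr1d1 was 1.92-fold higher, Elovl3 1.40-fold higher, Cry1 at least 1.70-fold lower and Usp2 1.36-fold lower. NRF2 targets had a median of 0.14 over 12 members at percentile 99.6, led by Gstm3 and the thioredoxin reductase Txnrd1 (2737.4 to 4765.0, 1.74-fold). Without Gstm3, which is also in the pericentral list, the median was 0.09 at percentile 97.3. Actin cytoskeleton and SRF targets had a median of 0.13 over 22 members at percentile 99.4, with 14 higher and 8 lower. The focal adhesion gene Zyx (1.71-fold), Tubb2a (1.60-fold), Actn1 (1.58-fold) and Anxa5 (1.55-fold) led, while Vcl was lower (-0.26). Negative signals of Zyx (290.2) and Anxa5 (296.7) were near the floor. The circadian list stood apart under 9 of 13 alternatives, with a median of 0.11 after quantile normalization, and the NRF2 list under 8, with 0.21 after quantile normalization. The actin list stood apart under 10, but its median was 0.05 with the mean over probe sets and 0.0039 without probe sets of shared or mixed probes.

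The remaining lists did not stand apart with the main settings. Adhesion and polarity genes had a median of 0.03 over 25 members at percentile 80.6, with the E-cadherin gene Cdh1 lower and Cldn2 1.94-fold higher. Extracellular matrix and TGF-beta targets had a median of 0.00 over 17 members at percentile 49.2 (0.19 at percentile 97.54 with the mean over probe sets), with Skil at 0.72 and Snai2 at -0.59. Ribosomal protein genes had a median of -0.12 over 24 members at percentile 47.3, which is where signal-matched random lists lie. Male-biased liver genes had a median of -0.14 over 19 members at percentile 21.8, with Susd4 2.58-fold higher and Uroc1 and Serpina12 (-0.74) lower. Female-biased genes had a median of -0.03 and a mean of 0.07 over 6 members at percentile 9.07, with Cyp3a44 at 0.81. Erythroid and platelet markers had a median of 0.09 over 7 members at percentile 74.6, with Slc25a37 at 0.74 and Car1 at -0.62.

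The tests of other cell types and of heat shock genes below were chosen after the values they use were seen. For the opposite shifts of pericentral and periportal genes, the tables argue against a signal-dependent scaling difference, since the 2 medians stayed 1.39 log2 apart after the loess correction. A different share of other cells would dilute hepatocyte genes of both zones alike, whereas the medians as deposited had opposite signs and lay 1.41 apart. Dilution alone therefore does not give this pattern, but these medians are the pattern itself and add no separate evidence. A candidate explanation is that the positive fraction held more cells from around the central vein, for example if plasmid uptake was higher there. Zonated genes outside the lists left this open, with a difference of 0.81 between zones. All 8 further pericentral genes were above 0 (median 0.72, percentile 100), though Mgst1 (0.0008) and Pon1 (0.08) barely so. Among them, Cyp2c54 and Gstm6 belong to families whose paralogs may not be separated. The 7 further periportal genes, 6 of them lower, had a median of -0.09 at percentile 49.1, with Igfbp2 (-0.01) and Tkfc (-0.03) near 0. An effect of Ezrin T567D on zonated genes and a difference in diet remain open and untested, since no fraction with a control plasmid was analysed here.

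For immediate early genes, the median was 0.53 after the loess correction, above the range of random lists, which argues against signal-dependent scaling. Handling may still differ between the 2 sorts: the 6 heat shock members of the list had a median of 0.36 against 0.42 for the list, with Hspa1a (0.87), Hspa1b (0.68) and Hspb1 (a bound of 0.85) higher and Dnajb1 (0.05), Hspa8 (-0.07) and Hsph1 (-0.11) near 0. Members on both sides decide nothing, and handling and Ezrin T567D cannot be told apart with 1 sort of each kind.

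Yap and TEAD targets measured in both arrays were higher in 5 of 7 cases, and one hypothesis was that genes which are also immediate early genes produced this. Targets above the floor in only 1 array, most of them lower by signal, are not among these 7. Without Ccn1, Gadd45b and Sgk1, of which Gadd45b has only a bound, the median stayed at 0.34, the value of Amotl2 in both cases, while the mean went from 0.29 to 0.12, the members higher to 3 of 5 and the percentile from 98.7 to 96.7. The call ended because the upper limit of random lists widened from 0.30 for 7 members to 0.36 for 5, not because the median moved, so the test does not decide this explanation. Activation of Yap by Ezrin T567D may be part of this pattern and was not tested by the 2 arrays.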
